A study of Mus musculus with 6 samples.

How the data were processed

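Total RNA from 3 Math1-Cre SmoM2 medulloblastomas and 3 SmoM2 control cerebella was extracted with TRIzol and column cleanup and made into libraries with a TruSeq RNA kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The submitters' processing notes name FastQC, Bowtie2 2.2.4, featureCounts and edgeR, with the mouse genome build mm10, and give no role or order for them. The annotation release, the counting options and the use of strand are not given in the sources used here. Reads shared by near-identical genes, by overlapping genes or by a gene and its antisense partner can therefore be split or assigned in ways that cannot be told from the counts.

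The authors' deposited table of all genes holds 43629 genes with 1 signal per gene and library, which is a read count divided by 1 size factor per library. This was found from the values: 100% of them were whole multiples of the smallest nonzero value of their library, to within 1e-06 of a read. The size factors obtained in this way ran from 0.841 to 1.38 and equalled the median-of-ratios factors recomputed from the recovered reads. The fold in the authors' deposited table of all genes is the ratio of the tumor mean to the control mean, as checked on the values. Its FDR column is the Benjamini-Hochberg adjustment of its p-value column, per the file headers and as checked on the values. The test behind these p-values is not given in the sources used here. A shorter list, also deposited by the authors, gives a log2 fold change, a p-value and an FDR per gene, per the file headers, with values that differ from those in the table of all genes. Neither the authors' folds nor their p-values entered the tests made here.

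Recovered reads summed to between 44902217 and 69550200 per library, and 26574 genes had a read in at least 1 library. The largest total is that of tumor library 1. A floor of 3 counts equals between 2.17 and 3.57 normalized counts, depending on the library, and covers counting error only. Replicates were compared before averaging. The chi-square per degree of freedom over genes was 10.9 to 13.7 between control libraries, 41.6 to 67.6 between tumor libraries and 791 to 1080 between the groups, so no pair of libraries was alike within sampling noise.

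The design fixed in advance named edgeR for raw counts and limma for normalized values. Because the deposited values are normalized, the main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(value + 1), over the 22117 genes with a value over 1 in at least 3 libraries. Fold changes are on this log2(value + 1) scale, which understates the change of genes with low counts. They are ratios of geometric means of value + 1. Where the libraries of a group differ widely, they can exceed the ratio of the arithmetic means, as for Hsd11b2 and Atoh1. The same holds for some falls. The control and tumor means were 989.2 and 100.1 for Kcne2, 96789 and 12569 for Ttr, and 675.5 and 90.1 for Slc4a5. The errors of the log2 fold changes are limma's standard errors. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and a second count required at least 2-fold change. On the recovered reads, edgeR 4.0.16 with its quasi-likelihood test and TMM called 6800 genes higher and 6611 lower among the same genes.

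The 35 gene lists of pathways and cell types, with 521 entries, were fixed before the data were examined, and some genes stand in more than 1 list. Lists with at least 4 tested members were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 35 lists. The correlation was then estimated per list, and fry was run as another alternative. Counts per list are given over all genes tested and adjusted over the list alone. Camera compares a list with all other genes tested.

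Named genes were chosen by a rule fixed before the data were examined. The rule always names a set of genes, namely Smo, Gli1, Gli2, Ptch1, Hhip, Atoh1, Mycn, Ccnd1, Ccnd2, Hsd11b1, Hsd11b2, Cyp7b1 and Ch25h, and 1 item that is not reported here. It adds the 10 largest rises and the 10 largest falls among called genes with at least 10 CPM in the higher group and no overlap between the groups, leaving out clone-named and predicted genes. From each list described, it takes up to 4 members: the called members with the 2 largest and the 2 smallest log2 fold changes, or those with the smallest p where fewer passed. A few other members named to identify the exceptions in a list, namely Bcl2, Fabp7 and Tmem119, and Eef1a1 and Cyp27a1 in the plots, were chosen after their values were seen.

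The gene-level script was tested on simulated data for the tumor against control comparison, with counts drawn for the real genes and 200 genes changed by known folds. Of 50 genes changed by each size, the test recovered 30% at 1.5-fold, 68% at 2-fold, 90% at 4-fold and 100% at 8-fold among 21203 genes tested, with 9 calls among 21003 unchanged genes. The changed genes were drawn only from genes above a minimum mean count, so recovery among genes with few reads was not tested. Far fewer genes changed than were called in the real comparison, so these rates need not hold there. In a simulation with 22117 genes, camera called 4 of 4 lists whose 15 genes rose 4-fold and 0 of 30 random lists. The simulated genes varied independently, whereas the correlation estimated in the real libraries was 0.914 for the oligodendrocyte list. The simulation therefore does not test false calls of lists whose genes vary together.

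The alternatives fixed in advance were other scalings (library totals, upper quartile), pseudocounts of 0.1 and 0.01, other filters (none, a value over 5, more than 1 CPM), an adjusted p under 0.01, a test against a 2-fold change, edgeR with median-of-ratios factors, limma-voom and DESeq2 1.42.0 on the recovered reads, a replicate block, and leaving out each library in turn. Chosen after seeing the data were edgeR with TMM on the recovered reads, the same with edgeR's own filter, and TMM scaling of the values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.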

Results

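RNA was sequenced in 3 libraries from medulloblastomas of Math1-Cre SmoM2 mice and 3 libraries from the cerebella of mice that carried the SmoM2 allele without the Cre recombinase. SmoM2 is a constitutively active form of Smoothened, the receptor that switches on the Hedgehog pathway. Math1-Cre turns the allele on in the lineage of cerebellar granule neuron progenitors. All 6 samples came from female mice on the C57BL/6 background at postnatal day 35, and the design text describes the controls as littermates. The recovered read totals were 47163711, 44902217 and 49455221 in the control libraries 1, 2 and 3, and 69550200, 49969867 and 52041234 in the tumor libraries 1, 2 and 3. Each value below is a normalized count, given as the mean ± SD of n = 3 libraries per group. The labels number the libraries of a group without stating that each is a separate mouse, so p-values measure only the spread between these samples, which may be technical.

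The comparison asks which transcripts differ between tumors driven by activated Smoothened and normal cerebellum. Most tested Hedgehog target genes (11 of 12), markers of granule neuron progenitors (11 of 14) and genes of DNA replication (20 of 21) and mitosis (21 of 21) were higher in the tumors, as were 13 of 14 markers of microglia and macrophages. All tested markers of mature granule neurons, GABAergic interneurons and oligodendrocytes were lower, as were 15 of 16 Purkinje cell markers and 25 of 26 genes of synaptic transmission. In limma's test with Benjamini-Hochberg adjustment, 6761 genes were higher and 6977 lower in tumor among 22117 tested. Of these, 3869 were higher and 4542 lower by at least 2-fold. All 3 tumors lay above all 3 controls for 7338 genes and below them for 7638, where chance gives 10% of genes in both directions together. Of 35 gene lists fixed in advance, 12 were higher and 13 lower than the other genes by camera with a preset correlation. With the correlation estimated from these libraries, camera called 0 of the 35 lists at an adjusted p under 0.05 and 7 at an unadjusted p under 0.05, while fry, which does not compare a list with other genes, called 31.

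**Figure D1:**
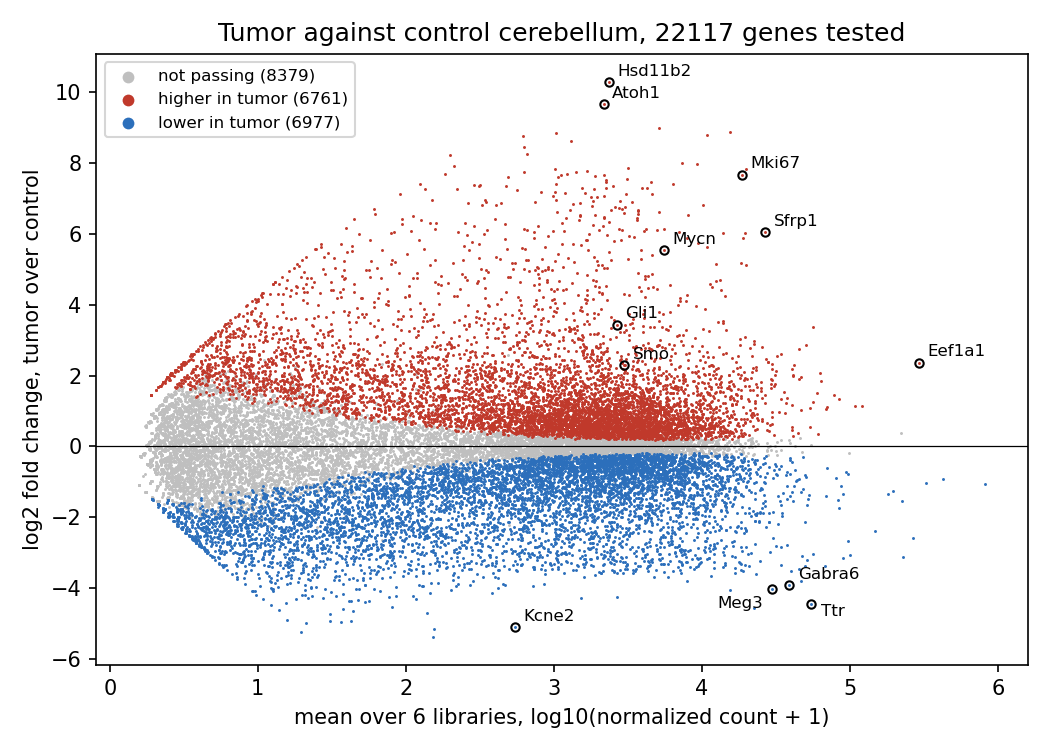
Each point is 1 of 22117 genes, with the mean normalized count of all 6 libraries on the horizontal axis (log10 of value + 1) and the log2 fold change of tumor over control on the vertical axis. Red points (6761) were higher and blue points (6977) lower in tumor at an adjusted p under 0.05, grey points did not pass, and open circles mark 12 genes by name.

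Smo, which encodes Smoothened, rose from 1012 ± 41.0 to 4969 ± 582 normalized counts, a 4.89-fold difference (log2 fold change 2.29 ± 0.10 SE, adjusted p = 5.92e-08). The gene (ENSMUSG00000001761) lies on chromosome 6 at 29735694 to 29761365 in mm10. Its count holds any reads of the SmoM2 allele that match the mouse gene. Gli1, a transcription factor and direct target of the pathway, rose 10.9-fold from 440.2 ± 21.1 to 4923 ± 1489 (log2 3.44 ± 0.18 SE, adjusted p = 1.58e-07). Gli2, the main activating transcription factor of the pathway, rose 16.6-fold, from 184.9 ± 11.8 to 3107 ± 522. Ptch1, which encodes a Hedgehog receptor that restrains Smoothened, rose 3.38-fold from 10609 ± 446 to 35971 ± 3814. Hhip, which encodes a protein that binds and sequesters Hedgehog ligand, rose 2.05-fold from 699.5 ± 90.3 to 1432 ± 127.

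Of the 12 Hedgehog target genes tested, 11 rose and 1, Bcl2 (log2 fold change 0.24, adjusted p = 0.0614), did not pass. Adjusted over the list alone, 12 were higher. The list had a median log2 fold change of 3.46 and an adjusted p of 1.21e-07 by camera, against adjusted p = 0.194 with an estimated correlation. Foxm1, a regulator of mitotic genes, rose 69.1-fold, and Sfrp1, which encodes a secreted modulator of Wnt signalling, rose 66.7-fold from 804.8 ± 167 to 52923 ± 1381. Mycn, an oncogene that drives granule progenitor proliferation, rose 46.5-fold from 234.5 ± 22.6 to 10935 ± 939. The D-type cyclin genes Ccnd2 and Ccnd1 rose 34.9-fold and 11.1-fold, to 38469.6 ± 755 and 25699.7 ± 2129. Of 19 genes for components of the pathway, 12 rose, 5 fell and 2 did not pass. Adjusted over the list alone, 13 were higher and 5 lower. The median log2 fold change of the components was 1.06 with an adjusted p of 0.0222 by camera, adjusted p = 0.479 with an estimated correlation. With the preset correlation it ran from 0.00355 to 0.0615 over 20 alternatives and missed the threshold with more than 1 CPM required in 3 libraries. Kif7, which encodes a ciliary kinesin of the pathway, rose 6.14-fold. Shh, the gene of the Sonic hedgehog ligand, fell 8.09-fold from 241.2 ± 23.4 to 29.7 ± 9.41, and Cdon, the gene of a Hedgehog co-receptor, fell 7.72-fold.

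**Figure D2:**
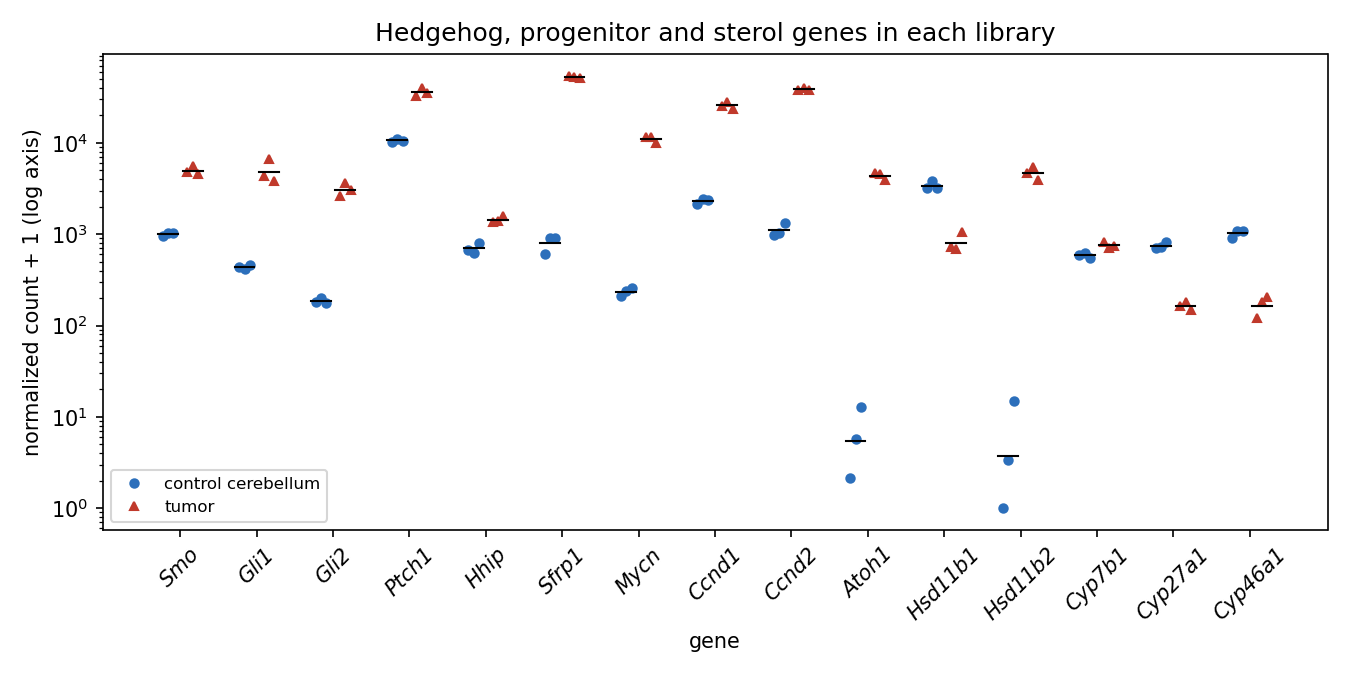
Normalized count + 1 on a log axis for 15 genes of Hedgehog signalling, granule progenitors and sterol metabolism, with 1 circle per control library, 1 triangle per tumor library and a line at each group's geometric mean. Hsd11b2 stands between 0 and 13.9 normalized counts in the controls and between 3923 and 5472 in the tumors, whereas Cyp7b1 differs 1.29-fold.

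All 21 genes tested for mitosis and G2/M rose, with a median log2 fold change of 6.62, and adjusted over the list alone 21 were higher (camera adjusted p = 1e-15, adjusted p = 0.217 with an estimated correlation). Top2a, which encodes a topoisomerase that untangles replicated chromosomes, rose 228-fold from 173.7 ± 32.5 to 39474 ± 3660. Mki67, the gene of the proliferation marker Ki-67, rose 205-fold from 188.9 ± 71.2 to 37198 ± 2550. The smallest rises of the list were those of Aurka, a mitotic kinase gene, at 56.5-fold, and Ccnb2, a mitotic cyclin gene, at 51.9-fold. Of 21 genes for DNA replication and G1/S, 20 rose and 1 did not pass, and adjusted over the list alone 21 were higher. Their median log2 fold change was 4.40 (camera adjusted p = 1.07e-14, adjusted p = 0.194 with an estimated correlation). Dtl, which encodes a substrate receptor that clears replication licensing factors, rose 189-fold, and Uhrf1, needed to maintain DNA methylation after replication, rose 157-fold. Ccne2, a cyclin gene of the G1/S transition, rose 2.50-fold.

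Of 14 markers of granule neuron progenitors, 11 rose, 2 fell and 1 did not pass, with the same counts adjusted over the list alone. Their median log2 fold change was 3.02 (camera adjusted p = 2.49e-05, adjusted p = 0.217 with an estimated correlation). Atoh1, the transcription factor gene that defines this lineage and is also known as Math1, rose from 5.88 ± 5.41 to 4361 ± 422 (809-fold, log2 9.66 ± 0.52 SE, adjusted p = 2.11e-07), with 16 reads in all controls together. Its log2 fold change was 8.99 without control replicate 1 and 10.28 without control replicate 3. Insm1, a zinc finger factor of neuronal progenitors, rose 252-fold from 76.8 ± 32.7 to 18396 ± 2317. The falls were those of Zic2, a transcription factor gene (1.26-fold), and Prom1, the gene of the surface protein CD133 (1.90-fold). Of 13 markers of newborn granule neurons, 11 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone. The median was 2.05 (camera adjusted p = 1.76e-05, adjusted p = 0.194 with an estimated correlation). Nhlh1, a helix-loop-helix factor of early postmitotic neurons, rose 505-fold from 20.9 ± 9.73 to 10214 ± 1219, and Igfbpl1 rose 445-fold from 52.0 ± 25.1 to 21774 ± 2829. Neurod1, a transcription factor gene that granule neurons keep as they mature, fell 1.499-fold.

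By the rule fixed for naming genes, the 10 largest rises were those of Hsd11b2, Atoh1, Nhlh1, Draxin, Myod1, Igfbpl1, Cst7, Ska1, Insm1 and Casc5. Draxin, which encodes a secreted axon guidance protein, rose 466-fold to 31176 ± 5551. Myod1, the master transcription factor gene of skeletal muscle, rose 458-fold from 4.41 ± 3.79 to 2073 ± 185, with 12 reads in the controls and 7240 in the tumors. Cst7, which encodes the protease inhibitor cystatin F of immune cells, rose 353-fold from 2.67 ± 1.88 to 1245 ± 454. Ska1 and Casc5, both encoding kinetochore proteins, rose 305-fold and 232-fold. The 10 largest falls were those of Kcne2, Fam107a, Ttr, Dao, Mybpc1, Slc4a5, Snhg11, Meg3, Sostdc1 and Prlr. The places of Kcne2, Ttr, Slc4a5, Sostdc1 and Prlr rest on tumor replicate 3. Without it their log2 fold changes were -2.69, -2.33, -2.30, -2.63 and -3.01. That of Gabra6, which is not among the 10, was -3.647 or lower in every alternative. Fam107a, which encodes an actin-binding protein, fell 23.7-fold from 42897 ± 4171 to 2072 ± 1395. Dao, the gene of the enzyme that degrades D-serine, fell 19.3-fold, and Mybpc1, a myosin-binding protein gene, fell 18.95-fold. Among long noncoding RNAs, Snhg11 fell 16.7-fold and the maternally expressed Meg3 fell 16.3-fold, from 55796 ± 8618 to 3525 ± 1237.

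Oxysterols are oxidized forms of cholesterol, and some of them bind Smoothened. Of 17 genes for enzymes of oxysterol and bile acid synthesis, 6 rose, 9 fell and 2 did not pass, with the same counts adjusted over the list alone. The median log2 fold change of the list was -0.52 and its mean 0.22, which differ in sign, and camera, whose direction was down, did not call it (adjusted p = 0.517). Over 20 alternatives this median ran from -1.28, with edgeR and its own filter, the test the design named for raw counts, to -0.43 with library totals. Hsd11b2, which encodes the dehydrogenase that inactivates glucocorticoids, had the largest rise of all genes that met the rule, from 5.43 ± 7.43 to 4687 ± 775 (1258-fold, log2 10.30 ± 0.76 SE, adjusted p = 1.62e-06). The control libraries held 15 reads of it in total. Its log2 fold change was 9.36 without control replicate 1, 11.30 without control replicate 3 and 12.71 with a pseudocount of 0.01. Hsd11b1, whose enzyme catalyses the opposite reaction, fell 4.18-fold from 3382 ± 349 to 821.1 ± 202 (adjusted p = 2.16e-06). Cyp7b1, an oxysterol hydroxylase gene, rose 1.29-fold from 587.0 ± 35.8 to 757.7 ± 57.3 (adjusted p = 0.0185). Over 20 alternatives the adjusted p of Cyp7b1 ran from 0.00552 to 0.0762, and it missed the threshold without control replicate 1 (0.0584), control replicate 3 (0.0762) or tumor replicate 1 (0.0609) and with upper-quartile scaling (0.0549). Ch25h, another cholesterol hydroxylase gene, did not pass at 7.27 ± 5.38 and 10.6 ± 0.876 (adjusted p = 0.312), where 19 and 37 reads allow little precision. Cyp46a1, whose enzyme starts cholesterol breakdown in neurons, fell 6.18-fold, and Sult2b1, a sterol sulfotransferase gene, fell 6.21-fold. Akr1d1, a steroid reductase gene, had 0 reads in all controls and 33 in the tumors and was at least 2.90-fold higher against a floor of 3 counts per control library. The list's median was -0.52 with Akr1d1 at that bound too.

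Of 22 genes for cholesterol synthesis and the regulator SREBP2, 2 rose, 14 fell and 6 did not pass, with the same counts adjusted over the list alone. Their median log2 fold change was -0.37 (camera adjusted p = 0.0331, adjusted p = 0.551 with an estimated correlation). With the preset correlation the adjusted p ran from 0.0145 to 0.145 over 20 alternatives, with no call without control replicate 3 (0.0762) or tumor replicate 3 (0.0571), with library totals, with more than 1 CPM required or with edgeR or DESeq2. Sc5d, which encodes a desaturase late in the pathway, fell 2.76-fold, and Hmgcs1, the gene of an early synthase, fell 2.42-fold from 23663 ± 4059 to 9708 ± 1017. Mvd, a mevalonate pathway gene, rose 1.599-fold. The other rise, that of Fdps (log2 fold change 0.30), lost its call in 5 of 20 alternatives. Of 10 target genes of the sterol sensor LXR and genes of cholesterol export, 3 rose, 3 fell and 4 did not pass, with the same counts adjusted over the list alone. The list was not called (adjusted p = 0.974), and its median of -0.10 and mean of 0.08 differ in sign. Srebf1, a transcription factor gene of lipid synthesis, rose 9.39-fold, and Apoe, the gene of a lipid-carrying apolipoprotein, rose 2.35-fold. Abcg4, a sterol exporter gene, fell 3.90-fold. The primary cilium is the organelle in which Smoothened signals. Of 33 genes for it, 14 rose, 9 fell and 10 did not pass, with the same counts adjusted over the list alone and no call for the list (adjusted p = 0.517). Ift140, needed for transport within cilia, rose 2.37-fold, and Bbs4, a gene of the BBSome that carries ciliary membrane proteins, fell 2.17-fold.

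All 16 markers of mature granule neurons fell, with a median log2 fold change of -3.16, and adjusted over the list alone 16 were lower (camera adjusted p = 2.56e-09, adjusted p = 0.352 with an estimated correlation). Gabra6, the gene of a GABA receptor subunit of granule cells, fell 14.97-fold from 72982 ± 5708 to 5196 ± 2389. Cbln3, which encodes a secreted synaptic organizer, fell 13.9-fold, and Rbfox3, the gene of the neuronal antigen NeuN, fell 2.03-fold. Of 16 Purkinje cell markers, 15 fell and 1 rose, with the same counts adjusted over the list alone and a median of -3.09 (camera adjusted p = 5.21e-07, adjusted p = 0.434 with an estimated correlation). Calb1, which encodes the calcium-binding protein calbindin, fell 10.4-fold from 91023 ± 4181 to 9250 ± 3904. The rise was that of Foxp2, a forkhead transcription factor gene, at 2.94-fold. All 13 markers of cerebellar GABAergic interneurons fell, 13 also adjusted over the list alone, with a median of -2.83 (camera adjusted p = 2.25e-07, adjusted p = 0.369 with an estimated correlation). Tfap2b, a transcription factor gene of these cells, fell 12.01-fold, and Slc6a5, the gene of a glycine transporter, fell 10.97-fold. Of 26 genes for synaptic transmission, 25 fell and 1 rose, with the same counts adjusted over the list alone and a median of -1.90 (camera adjusted p = 8.21e-10, adjusted p = 0.264 with an estimated correlation). Grin2a, an NMDA receptor gene, fell 11.3-fold, and Syt1, which encodes the calcium sensor of synaptic vesicle release, fell 9.52-fold. Stx1a, a gene of the vesicle fusion machinery, rose 3.99-fold. Beside these lists, the share of reads from the mitochondrial genome was 6.95% ± 0.111 in control and 3.07% ± 0.658 in tumor. Of the 13 mitochondrially encoded transcripts, 12 fell and 1 did not pass, with the same counts adjusted over the list alone and a median of -1.04 (camera adjusted p = 0.000719, adjusted p = 0.534 with an estimated correlation). Transcripts mt-Nd3 and mt-Nd2, both for subunits of respiratory complex I, fell 4.24-fold and 2.89-fold.

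All 14 oligodendrocyte markers fell, 14 also adjusted over the list alone, with a median log2 fold change of -2.99 (camera adjusted p = 1.26e-06, adjusted p = 0.456 with an estimated correlation). Ermn, a gene of the myelin cytoskeleton, fell 9.92-fold, and Cnp, which encodes a myelin enzyme, fell 4.92-fold from 30721 ± 3146 to 6336 ± 1517. Of 7 markers of oligodendrocyte precursors, 4 rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone and a median of 0.996. Camera called the precursor list (adjusted p = 0.0313, adjusted p = 0.534 with an estimated correlation), but not without tumor replicate 2 (0.0518) nor with more than 1 CPM required (0.0708, the highest over 20 alternatives, the lowest being 0.00387). Pdgfra, the receptor gene that marks these precursors, rose 9.60-fold from 2120 ± 203 to 20311 ± 884, and Olig2, a transcription factor gene of the lineage, rose 3.32-fold. The gene that fell was Sox10, another transcription factor gene of the lineage, with a log2 fold change of -0.52 (adjusted p = 0.0249). Its call was lost in 5 of 20 alternatives: with library totals (0.0875) and without control replicate 2 (0.0712), control replicate 3 (0.106), tumor replicate 1 (0.0785) or tumor replicate 3 (0.0761). Of 14 markers of astrocytes and Bergmann glia, 10 fell, 3 rose and 1 did not pass, with the same counts adjusted over the list alone and a median of -0.73. The astrocyte list was called (camera adjusted p = 0.0331, adjusted p = 0.434 with an estimated correlation), but not with more than 1 CPM required (0.0615, the highest over 20 alternatives, the lowest being 0.0109). Gdf10, a Bergmann glia gene, fell 8.61-fold. The rises were those of Sox9, a glial transcription factor gene (3.19-fold), Gfap, which encodes the intermediate filament of reactive astrocytes (3.10-fold), and Fabp7, a fatty acid binding protein gene of radial glia (log2 fold change 0.69).

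**Figure D3:**
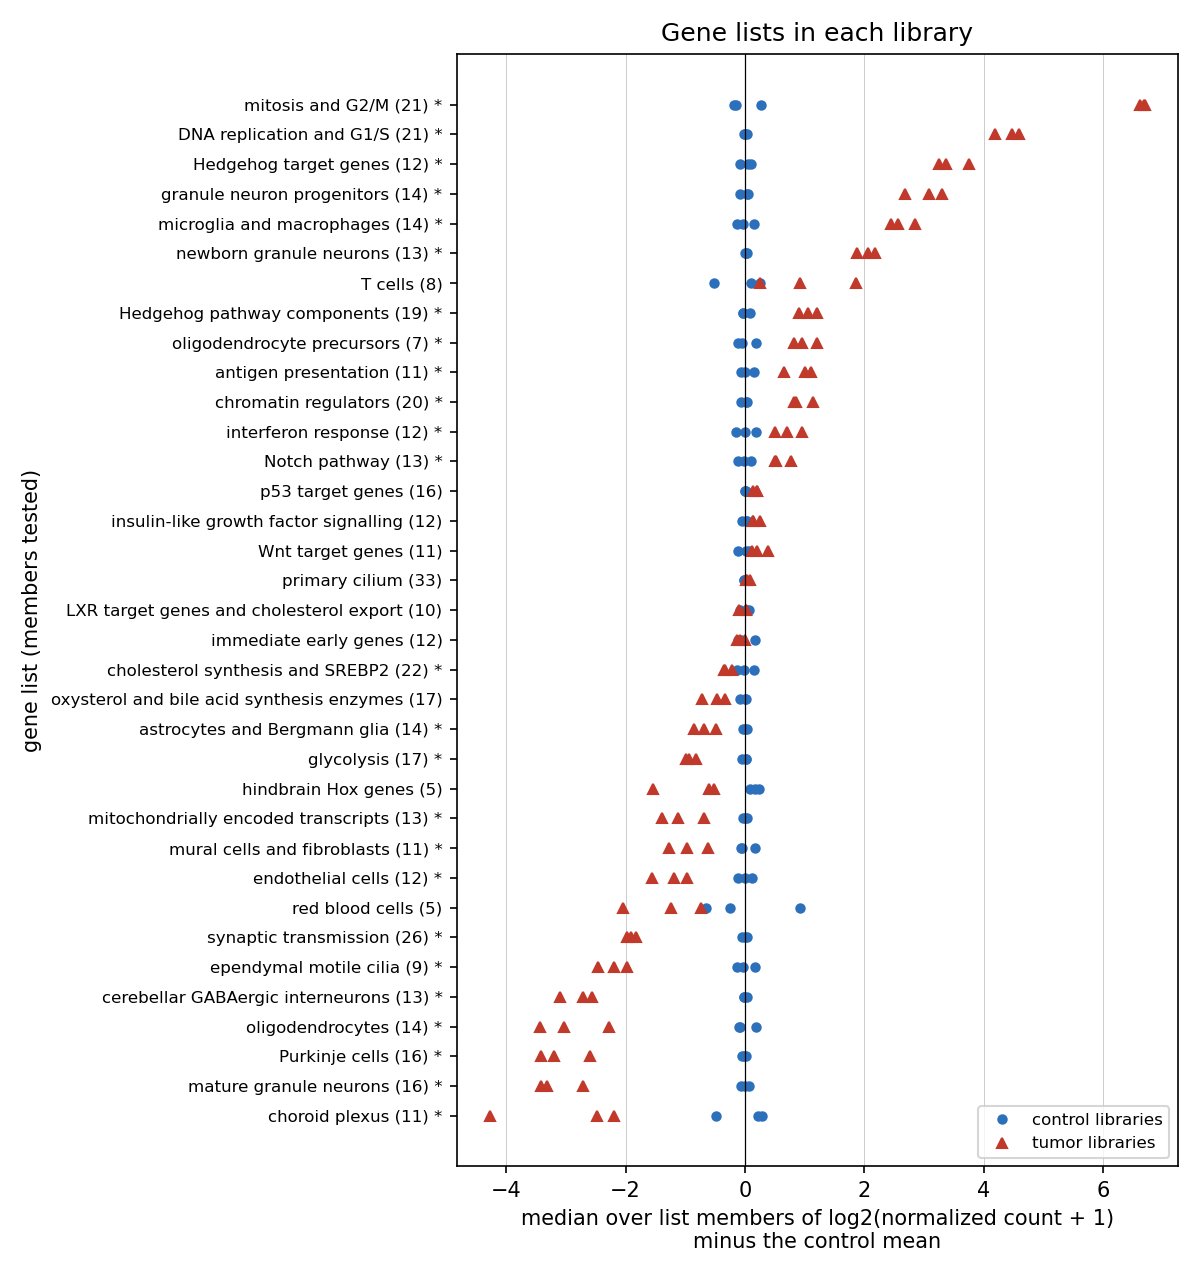
For each of 35 gene lists, with the number of members tested in parentheses, points show the median over members of log2(normalized count + 1) minus the control mean, with 1 circle per control library and 1 triangle per tumor library. Lists marked with an asterisk passed camera with the preset correlation. The mitosis and G2/M list stands between 6.63 and 6.70 in the tumors and the choroid plexus list between -4.28 and -2.19.

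Of 14 markers of microglia and macrophages, 13 rose and 1, Tmem119 (log2 fold change 0.32, adjusted p = 0.198), did not pass, with the same counts adjusted over the list alone. The median log2 fold change was 2.63 (camera adjusted p = 5.28e-07, adjusted p = 0.352 with an estimated correlation). Aif1, which encodes the microglial marker Iba-1, rose 9.53-fold from 138.9 ± 41.5 to 1299 ± 209, and C1qa, a complement gene, rose 9.26-fold from 388.3 ± 72.6 to 3585 ± 490. The smallest called rises were those of Itgam (1.85-fold) and P2ry12 (1.45-fold, limma adjusted p = 0.0164). For P2ry12 the single libraries of the groups overlapped, and its call was lost in 4 of 20 alternatives. Of 8 T cell markers, 1 rose and 7 did not pass, with the same counts adjusted over the list alone and no call for the list (adjusted p = 0.204). The rise was that of Cd4, the gene of a co-receptor of helper T cells that myeloid cells can also carry, from 20.4 ± 4.68 to 676.8 ± 102 (31.9-fold). Cd3e, the gene of a T cell receptor chain, had 3 reads in the controls and 14 in the tumors (adjusted p = 0.168), and it passed without control replicate 1 (0.0487, the lowest of 17 alternatives, the highest being 0.437). Lck, which encodes a kinase of T cell receptor signalling, had 54 and 118 reads (adjusted p = 0.139) and also passed without control replicate 1 (0.0394, the lowest of 19 alternatives, the highest being 0.467). Of 12 genes of the interferon response, 7 rose and 5 did not pass, with the same counts adjusted over the list alone and a median of 0.77. The call of the interferon list (camera adjusted p = 0.026, adjusted p = 0.456 with an estimated correlation) was lost with edgeR, DESeq2 or more than 1 CPM required, and over 20 alternatives the adjusted p ran from 0.0148 to 0.23. Cxcl10, a chemokine gene, rose 32.2-fold, and Mx1, an antiviral gene, rose 7.65-fold. The smaller rises of Ifi44 and Oasl2 (log2 fold changes 0.87 and 0.68) lost their calls in 6 and 1 of 20 alternatives. Of 11 genes of antigen presentation, 8 rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone and a median of 0.92. For antigen presentation the call (camera adjusted p = 0.0331, adjusted p = 0.551 with an estimated correlation) was lost without control replicate 2 (0.0533) or tumor replicate 2 (0.0551), with more than 1 CPM required and with edgeR or DESeq2, and the adjusted p ran from 0.013 to 0.256 over 20 alternatives. Cd74, which encodes the MHC class II invariant chain, rose 3.49-fold, and H2-D1, an MHC class I gene, fell 1.57-fold. The rise of Psmb9 (log2 fold change 0.80) lost its call in 5 of 20 alternatives.

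Of 11 choroid plexus markers, 9 fell, 1 rose and 1 did not pass. Adjusted over the list alone, 10 were lower and 1 higher. Their median log2 fold change was -3.20, or -2.44 without tumor replicate 3. The call of this list (camera adjusted p = 0.0177, adjusted p = 0.551 with an estimated correlation) was lost with edgeR or DESeq2, and the adjusted p ran from 0.00245 to 0.147 over 20 alternatives. Ttr, which encodes the thyroxine carrier transthyretin made by the choroid plexus, fell 21.7-fold (adjusted p = 0.0184), with 20585 and 16890 normalized counts in tumors 1 and 2 and 231.2 in tumor 3. Kcne2, a potassium channel subunit gene, fell 34.2-fold (adjusted p = 0.0182) and had 171.9, 128.5 and 0 normalized counts in tumors 1, 2 and 3. Slc4a5, a bicarbonate transporter gene, fell 17.5-fold (adjusted p = 0.0139), Sostdc1, a secreted BMP antagonist gene, 15.9-fold, and Prlr, the prolactin receptor gene, 15.3-fold. The log2 fold changes of Ttr, Kcne2, Slc4a5, Sostdc1 and Prlr were -2.33, -2.69, -2.30, -2.63 and -3.01 without tumor replicate 3. Without tumor replicate 1 those of Ttr, Kcne2, Slc4a5 and Sostdc1 were -5.57, -6.40, -4.99 and -4.60, and without tumor replicate 2 they were -5.42, -6.20, -5.11 and -4.76. Without control replicate 2 the adjusted p rose to 0.0615 for Ttr, 0.061 for Kcne2 and 0.05 for Slc4a5, and without control replicate 3 to 0.0604 for Ttr and 0.059 for Kcne2. Kcne2 also missed the threshold with DESeq2 and with pseudocounts of 0.1 and 0.01. Over 20 alternatives it ran from 2.72e-05 to 0.0615 for Ttr, from 1.82e-05 to 0.104 for Kcne2 and from 2.91e-05 to 0.05 for Slc4a5. The rise in the list was that of Otx2, a homeobox gene, at 3.54-fold from 1238 ± 67.1 to 4433 ± 860.

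Of 9 genes of ependymal motile cilia, 7 fell and 2 did not pass, and 8 were lower adjusted over the list alone. Their median log2 fold change was -2.26 (camera adjusted p = 0.00187, adjusted p = 0.352 with an estimated correlation), and Dnah11, a dynein gene of motile cilia, fell 10.2-fold. Of 12 endothelial markers, 11 fell and 1 did not pass, with the same counts adjusted over the list alone and a median of -1.22 (camera adjusted p = 0.000926, adjusted p = 0.534 with an estimated correlation). Abcb1a, a drug efflux pump gene of the blood-brain barrier, fell 3.31-fold. Of 11 markers of mural cells and fibroblasts, 8 fell and 3 did not pass, with the same counts adjusted over the list alone and a median of -1.06. The call of this list (camera adjusted p = 0.0177, adjusted p = 0.551 with an estimated correlation) was lost with edgeR, and the adjusted p ran from 0.00841 to 0.103 over 20 alternatives. Acta2, the smooth muscle actin gene, fell 5.27-fold. The fall of Dcn (log2 fold change -0.31) lost its call in 5 of 20 alternatives. All 5 red blood cell genes fell, 5 also adjusted over the list alone, with a median of -1.44 (-1.74 to -0.97 over 20 alternatives), but camera did not call the list (adjusted p = 0.0988). It passed without control replicate 2 (0.0402) and with the replicate block (0.0114, the lowest over 20 alternatives, the highest being 0.464). Among its genes, Hba-a1, Hba-a2 and Hbb-bs, which encode globins, lost their calls in 6, 4 and 1 of 20 alternatives, with adjusted p up to 0.108, 0.0833 and 0.0751, and the single libraries of the groups overlapped for Hba-a1 and Hba-a2. Without tumor replicate 2 all 3 lost the call. Alas2, needed for heme synthesis in red cells, fell 3.06-fold from 790.2 ± 419 to 253.1 ± 101.

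Of 17 genes of glycolysis, 15 fell and 2 rose, with the same counts adjusted over the list alone and a median log2 fold change of -0.91 (camera adjusted p = 9.64e-05, adjusted p = 0.194 with an estimated correlation). Eno2, the gene of the enolase of neurons, fell 10.02-fold from 33158 ± 567 to 3391 ± 956. The rises were those of Hk2, a hexokinase gene, at 7.39-fold from 1435 ± 45.7 to 10613 ± 569, and Ldha, a lactate dehydrogenase gene, at 1.49-fold. Of 20 chromatin regulators, 16 rose, 3 fell and 1 did not pass, with the same counts adjusted over the list alone and a median of 0.86 (camera adjusted p = 0.000343, adjusted p = 0.233 with an estimated correlation). The Polycomb genes Ezh2 and Cbx2 rose 13.4-fold and 10.4-fold, while their paralogs Ezh1 and Cbx7 fell 2.33-fold and 6.00-fold. Of 13 Notch pathway genes, 7 rose, 2 fell and 4 did not pass, with the same counts adjusted over the list alone and a median of 0.58. The call of the Notch list (camera adjusted p = 0.0448, adjusted p = 0.551 with an estimated correlation) was lost in 7 of 20 alternatives, among them the fit without tumor replicate 2 (0.127), and the adjusted p ran from 0.0133 to 0.127. Dll3, a Notch ligand gene, rose 28.9-fold, and Hes5, a Notch target gene, rose 16.5-fold.

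Camera did not call the remaining lists. Of 16 p53 target genes, 6 rose, 5 fell and 5 did not pass, with 7 higher and 5 lower adjusted over the list alone (adjusted p = 0.517). Eda2r, a gene of the TNF receptor family, rose 63.7-fold, and Phlda3, which encodes an inhibitor of Akt, fell 2.39-fold. Of 11 Wnt target genes, 4 rose, 3 fell and 4 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.811), and the median of 0.11 and mean of -0.06 differ in sign. Nkd1, which encodes a Wnt inhibitor, rose 9.83-fold, and Sp5, a transcription factor gene, fell 5.32-fold. Of 12 genes of insulin-like growth factor signalling, 6 rose, 4 fell and 2 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.654). Irs1, the gene of a receptor adaptor, rose 6.26-fold, and Igf2r, whose receptor clears the ligand IGF-II, fell 2.81-fold. Of 12 immediate early genes, 4 rose, 4 fell and 4 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.854). Egr2 rose 11.7-fold and Arc, which responds to neuronal activity, fell 5.46-fold. Of 5 hindbrain Hox genes tested, limma called 0 in its main setting, also adjusted over the list alone, with 1 at an unadjusted p under 0.05 (list adjusted p = 0.615). That gene, Hoxa5, had 6 reads in the controls and 0 in the tumors, and its adjusted p of 0.0582 ran from 0.0144 to 0.192 over 16 alternatives. It was called lower by edgeR (0.0455 with TMM, 0.0444 with median-of-ratios factors), by limma-voom (0.0417), by limma without a filter (0.0351), and with a pseudocount of 0.1 (0.0236) or 0.01 (0.0144). The Hox list's median was -0.94 (-2.17 to -0.53 over 17 alternatives), or -0.13 with Hoxa5 at its floor.

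The authors' deposited table of all genes gives an FDR under 0.05 to 12229 genes, 6012 with a fold above 1 and 6217 below. Of these, 12190 were called here in the same direction. The authors' deposited shorter list holds 2654 genes, 1315 higher and 1339 lower in tumor, with log2 fold changes of at least 1.62 in size and FDR values up to 0.0499. The list was chosen on these samples and is not independent evidence of direction. Of its genes, 2634 were tested here, 2606 were called in the same direction, 2 in the opposite direction and 26 were not called. Across those 2634 genes, which are not independent replicates, the log2 fold changes of the authors' deposited list and those computed here had a Pearson r of 0.988.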

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

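Decided on only after the result was seen were edgeR with TMM on the recovered reads, with and without its own filter, and TMM scaling of the values. With its own filter, edgeR with TMM is the test the design had named for raw counts. It called 6543 genes higher and 6227 lower, and with it camera called 9 lists higher and 10 lower. Leaving out 1 library at a time gave 6110 to 6700 genes higher and 6109 to 6969 lower, 3652 to 3856 and 4122 to 4568 by at least 2-fold, and 9 to 12 lists higher and 12 to 14 lower. Requiring a change beyond 2-fold in the test itself left 2188 genes higher and 2449 lower, as a stricter hypothesis must. With more than 1 CPM in 3 libraries, which tested 14849 genes, 7 lists were higher. Camera with an estimated correlation called 0 lists higher and 0 lower. In the other alternatives the gene counts ran from 5554 to 7369 higher and from 5577 to 7448 lower. Of 163 genes chosen by the naming rule, 155 were called, and 14 of these lost the call in at least 1 alternative. No named gene that was called changed direction in the alternatives run. Of the 25 lists called, 9 lost the call in at least 1 alternative with the preset correlation. Camera's direction for the LXR list, not called in any alternative, turned to up with library totals (median -0.0036), edgeR with median-of-ratios factors (-0.0992) and DESeq2 (-0.0993), and without control replicate 3, tumor replicate 1 or tumor replicate 3 (medians from -0.112 to -0.0409 over all fits leaving out 1 library). That of the immediate early genes turned without control replicate 2 or tumor replicate 3 (medians from -0.477 to -0.0395 over all such fits). The cause was not tested. Whether the replicate numbers pair the libraries could not be settled. The correlations of deviations between same-numbered libraries over 13952 genes were 0.135, 0.0369 and -0.0539. Between libraries of different numbers they ran from -0.111 to 0.0747. The same-numbered values were thus not high in every pair, but 3 libraries per group are too few to exclude shared litters. With the replicate block, 6744 genes were higher and 6943 lower, 3846 and 4496 by at least 2-fold, 12 lists were higher and 14 lower, and the red blood cell list was called (adjusted p = 0.0114). Depth limits the genes with few reads, such as Ch25h, the T cell receptor genes and the Hox genes, for which folds depend on the pseudocount.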

Other observations

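Tests chosen only after the result was seen were both tests on the marker lists, the test of size factors and the correlation with parent genes for pseudogenes, and the test of mature neurons for Meg3, Rian and Mirg; the genes named in the next paragraph, and Rian, Mirg and the 5 other genes of their cluster, were also chosen after their values were seen. The segment test on chromosome 12 was set after the medians of whole chromosomes were known, but before those of the neighbouring genes.

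Genes for the protein part of the cytosolic ribosome rose together in the tumors. All 76 tested genes of this kind were called higher by limma, with a median log2 fold change of 2.002, from 0.98 for Rpl27a to 3.03 for Rplp0, and all 76 were higher with library totals (median 2.10), upper-quartile scaling (1.92) and TMM scaling (2.02). Many have processed pseudogenes that share their sequence, so single values are uncertain. Eef1a1, which encodes the translation elongation factor that brings aminoacyl-tRNA to the ribosome, rose 5.16-fold from 94366 ± 268 to 493540.1 ± 96093 normalized counts (n = 3 per group). Xist, the noncoding RNA of X inactivation, rose 2.17-fold from 43990.1 ± 5714 to 95463 ± 12079 in these female mice (adjusted p = 4.43e-05). Igf2, an imprinted growth factor gene, fell 1.59-fold from 12168 ± 1431 to 7613 ± 423 (adjusted p = 0.0002). Median log2 fold changes of genes per chromosome, tumors against controls, ran from -0.08 on chromosome 18 to 0.23 on chromosome 17 (-0.17 to 0.27 in single tumors), where a gain of 1 copy in all cells would give 0.585 and a loss -1.

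Of the 2654 genes of the authors' deposited shorter list, 10 had 0 recovered reads in all 6 libraries of the authors' deposited table of all genes. The authors' deposited list gives them log2 fold changes from 3.65 for Cmtm2a to -6.74 for Gm23508. In the other direction, 2916 genes called here with a change above the list's smallest size are not on it.

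Marker lists of normal cerebellar cell types fell by different amounts. The medians of mature granule neurons, Purkinje cells, oligodendrocytes and GABAergic interneurons were close (-3.16, -3.09, -2.99 and -2.83). Those of ependymal motile cilia (-2.26), endothelial cells (-1.22), mural cells and fibroblasts (-1.06) and astrocytes and Bergmann glia (-0.73) fell less. A single dilution of all normal cells by tumor cells would lower every list alike. The astrocyte median lay above that of mature granule neurons by 2.47 on the log2 scale (SD 0.221 over 3 tumors), which dilution alone would not give. The 2 lists were compared with their medians known, so the gap is a description, and 3 astrocyte markers rose. Unequal carry of choroid plexus may account for part of the fall of the choroid plexus list, but does not bear on the gap between astrocytes and granule neurons. The choroid plexus list median varied by 2.08 over the tumors, against at most 1.16 for any brain parenchyma list. This range rests on tumor 3, at -4.275 against -2.195 and -2.476 in tumors 1 and 2. In tumor 3, Ttr, the most abundant of these markers, stood at 231.2 normalized counts, against 16890 and 20585 in the other tumors. Tumor biology itself, such as reactive glia, was not tested apart.

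Processed pseudogenes were called higher 449 times and lower 70 times among 1512 tested, whereas protein-coding genes were called 5759 times higher and 5949 times lower among 16755. The authors' size factors as the cause are argued against, since 1 factor per library moves genes of the same level alike, yet the median log2 fold change of the tested processed pseudogenes exceeded that of protein-coding genes of the same level by 1.23 (mean over 20 bins of level and 3 tumors, SD 0.161 over the tumors). Reads shared with parent genes may contribute. Only 212 of the tested pseudogenes were paired with a tested parent gene, by their names, and the parent comparisons cover these alone. Of the 108 called among them, 98.1% had the sign of their parent gene. With the parents shuffled the mean was 92.9% and the 95th percentile 94.4%. These signs decide little, because the parent had a fold change above 1 in 105 of the 108 pairs and several pairs share a parent. Many of the parents are the ribosomal protein genes that all rose. Across 212 pairs the log2 fold changes had a Pearson r of 0.509, against a 95th percentile of 0.135 when whole parents were shuffled. Transcription of the pseudogenes themselves was not tested and stays open.

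Meg3, Rian and Mirg, noncoding RNAs expressed from the maternal copy of an imprinted cluster on chromosome 12, fell 16.3-fold, 11.4-fold and 11.04-fold. The fall was not confined to them: of 5 other tested genes in or beside the cluster, Dlk1 and Dio3, expressed mainly from the paternal copy, and the noncoding Dio3os were called lower (4.496-fold, 4.52-fold and 5.58-fold, Dio3 with 16 reads in the controls and 1 in the tumors), and Rtl1 and Begain were not called. Loss of a wider segment is argued against, since the median log2 fold change of 38 protein-coding neighbours within 2 Mb was 0.05, with a bootstrap interval whose lower bound was -0.188. These neighbours lie outside the imprinted genes, so a loss confined to the cluster was not tested. Fewer mature neurons could lower these RNAs, but their mean log2 fold change of -3.67 stood close to the 10th percentile of mature neuron markers (-3.58) and below it by less than the spread of the 3 RNAs. That explanation cannot be told apart from an added loss of expression, as the 3 values are too few, and imprinting was not measured.

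The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 13738 genes, 8411 by at least 2-fold, and 25 lists, and in each case it was the 1 split with a result as large. The highest of the other splits called 1 gene, 1 gene by at least 2-fold, and 20 lists. Each of the other splits puts 2 libraries of 1 group beside 1 of the other, so part of the tumor difference stays in it.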
